A study of Homo sapiens with 6 samples.

How the data were processed

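Satellite repeats were measured in 6 libraries of SW620, a human cell line established from a lymph node metastasis of a colon adenocarcinoma. Per the labels, the cells were sampled in 2D culture before xenografting, as a subcutaneous xenograft in Nu/Nu mice, and in 2D culture after the xenograft. RNA and DNA were each sequenced at all 3 stages, which gives 1 library per group and no replicates. Per the labels' protocols, RNA was purified with TRIzol and sequenced by Helicos single-molecule sequencing under a digital gene expression protocol, and DNA was isolated with a DNeasy kit and sequenced on the same platform under its DNA protocol. Single-molecule sequencing reads molecules without amplification by PCR.

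The authors deposited 1 table in RPM (reads per 1000000 reads of the library total), with 1 row per satellite locus. Its row names give 9566 satellite loci of 24 RepeatMasker families with chromosome, start, end and strand. The build is hg19 per the submitters' processing notes, and coordinates are given in that build. The aligner, the handling of reads with several matches, the strand rule, the reads counted in each library total and the treatment of mouse reads are not given in the sources used here. The table holds 0 gene rows, so lists of genes fixed before the data were examined (stroma, hypoxia, interferon and others) could not be measured. Gene annotation of the loci was not used here, because the reference tables at hand are of another build.

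Whole reads were recovered from the deposited RPM values. Within each library, 100% of nonzero values were whole multiples of the smallest value within a tolerance of 0.01 reads, and the total that makes this value a single read was taken as the library total. The totals were 157326, 1077925 and 240046 reads for RNA before, during and after xenograft growth, and 4355426, 3231173 and 3080853 reads for DNA. A single read was worth 6.36, 0.928 and 4.17 RPM in the RNA libraries and 0.230, 0.309 and 0.325 RPM in the DNA libraries. A locus without a read could therefore hold up to 19.1, 2.78 or 12.5 RPM in RNA, taking 3 reads as the limit, and up to 0.689, 0.928 or 0.974 RPM in DNA.

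A read counted at a locus is called a hit. Of 3811 loci with 5 or more hits over the 6 libraries, 698 (18.3%) held values identical to those of another locus of their family in all libraries, so a read with several matches appears to be counted at each. Family values are sums of hits over loci, and a read can enter such a sum more than once. Ratios carry 95% exact conditional binomial (Clopper-Pearson) intervals on the recovered hits, and levels in RPM carry exact Poisson intervals. These intervals cover counting error only, treat hits as independent reads and are too narrow where reads are shared; they hold no spread between cultures or animals. Against a family or locus with 0 hits, the fold is a bound computed with 3 reads in its place. The lower 95% limit, which uses the 0 itself, lies below this bound and is given beside it.

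Single loci were compared on the log2(RPM + 5) scale among loci with at least 20 RPM in either library, and a 2-fold difference was counted in each direction. This scale understates the difference of low loci, and where 20 RPM was reached in 1 library only, a 2-fold difference is likely by that choice. The rule was fixed before the data were examined, as was what to name: HSATII and each family in every comparison, the 12 highest and 12 lowest log2 ratios in RNA, and the 5 highest and 5 lowest in DNA. The text gives these lists of loci by range and family, with single loci as examples. No p-value is given, since no group has replicates. Tested on simulated data with 4-fold differences at known loci, the size rule found 91.4%, 96.1% and 93.0% of them in the RNA comparisons (xenograft against the culture before, culture after against xenograft, culture after against the culture before). It found 100% in each DNA comparison. Of unchanged simulated loci, 17.8%, 12.5% and 31.9% passed 2-fold through counting error alone in those RNA comparisons, against 0 in DNA.

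The design had assumed scaling to the total over all rows. As the rows hold satellites only, the deposited RPM was used in its place. Alternatives were scaling by TMM (edgeR 4.0.16) and by size factors (DESeq2 1.42.0), both over satellite loci, totals without satellite hits, another pseudocount, other RPM minimums, and a count test on recovered reads (exact conditional binomial test with Benjamini-Hochberg adjustment). Computations used R 4.3.3, Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, with figures drawn in matplotlib 3.10.9.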

Results

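RNA and DNA of SW620 colon cancer cells were sequenced at 3 stages, in culture before xenografting, as a mouse xenograft and in culture afterwards, to follow HSATII as the cells moved between the environments. HSATII (human satellite II) is a simple satellite of pericentromeric heterochromatin. The 6 libraries, 1 per group, held 157326 to 1077925 reads of RNA and 3080853 to 4355426 reads of DNA. Hits at satellite loci, where a read can count more than once, were set against the reads of each library. In RNA they came to 0.504% before xenografting (793 hits, Wilson score 95% interval 0.470 to 0.540%). They came to 7.29% in the xenograft (78581 hits, 7.24 to 7.34%) and 1.30% after it (3128 hits, 1.26 to 1.35%). In DNA the shares were 0.854% (37190 hits, 0.845 to 0.863%), 9.88% (319346 hits, 9.85 to 9.92%) and 10.4% (319998 hits, 10.35 to 10.42%). Ratios below compare single libraries, their 95% intervals cover counting error only, and no difference could be set against a spread between replicates.

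HSATII RNA was at 19.1 RPM before xenografting (3 hits, interval 3.93 to 55.7) and at 6908 RPM in the xenograft (7446 hits, 6752 to 7066), a ratio of 362 (124 to 1757). Hits fell on 325 of the 399 HSATII loci in the xenograft against 3 in the culture before. The locus with the most HSATII RNA, at chromosome 10, 42598547 to 42601361 (hg19, minus strand), had 362 RPM in the xenograft (390 hits) and 0 in the culture before, at least 18.97-fold higher (lower 95% limit 15.4). The other satellites as a whole were 13.1-fold higher in the xenograft (12.3 to 14.1). HSATII took 9.48% of the satellite hits in the xenograft and 0.378% in the culture before.

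Centromeric alpha satellite (ALR/Alpha) RNA was 22.2-fold higher in the xenograft than in the culture before (20.04 to 24.6; 2371 and 52602 RPM). The simple pericentromeric repeats (CATTC)n and (GAATG)n were 107-fold (36.6 to 520) and 94.2-fold (36.8 to 346) higher, SAR at least 41.0-fold and HSATI at least 10.1-fold (lower 95% limits 33.3 and 8.12). Beta satellite (BSR/Beta) was 4.92-fold higher (4.08 to 5.99), CER 6.48-fold (3.49 to 13.6), ACRO1 4.17-fold (2.94 to 6.14), GSATX 3.99-fold (2.07 to 8.83) and the gamma satellite GSATII 2.96-fold (2.22 to 4.04). SATR1, SATR2 and SST1 were 3.36-fold (2.15 to 5.56), 2.00-fold (1.28 to 3.28) and 1.99-fold (1.44 to 2.81) higher. MSR1, with 30 hits against 0, was at least 1.46-fold higher with a lower 95% limit of 1.12, but TMM brought that limit to 0.989 and size factors to 0.783. SUBTEL_sa, with 3 hits before and 1 in the xenograft, had a ratio of 0.0487 (0.000927 to 0.606). For the other 8 of the 24 families the interval held 1. Subtelomeric TAR1 was at 0.888 (0.625 to 1.29), HSAT4 at 0.988 (0.549 to 1.93), HSAT5 at 2.55 (0.656 to 21.9) and LSAU at 2.43 (0.786 to 12.2), and HSAT6, with 5 hits against 0, has no ratio. GSAT was at 1.10 (0.689 to 1.86), D20S16 at 1.04 (0.470 to 2.73) and REP522 at 1.40 (0.978 to 2.07), but GSAT and D20S16 turned to below 1 under TMM (0.977 and 0.924) and all 3 under size factors (0.773, 0.732 and 0.984).

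By locus, 336 of 377 satellite loci were at least 2-fold higher in xenograft RNA than in the culture before and 4 were lower. Most, 337 of the 377, reached 20 RPM through the xenograft alone. Of the 40 at 20 RPM in the culture before, 10 were higher and 4 lower, but picking loci by that library favours lower values in the xenograft. The count test, which compares these libraries only, called 165 loci higher and 0 lower. Of the 12 with the highest log2 ratios (6.25 to 8.84), 11 were alpha satellite arrays. The first, at chromosome 8, 43816164 to 43838878, had 2291 RPM in the xenograft and 0 in both cultures, and an array at chromosome X, 61682015 to 61736573, had 12.7, 3984 and 4.17 RPM before, during and after. The other was the SAR locus at chromosome 8, 43092746 to 43097520, with 0, 782 and 4.17 RPM. The 12 lowest (−1.53 to −0.39) rested on 4 to 21 hits in the culture before, and the counting intervals of all 12 ratios held 1. They included 3 TAR1 loci of chromosome 9 and the REP522 locus at chromosome 22, 22477210 to 22479804, with 133, 82.6 and 233 RPM. Scaling over satellite loci shifted the log2 ratio of every family by −0.17 (TMM) or −0.51 (size factors) and turned none of the family ratios whose intervals excluded 1. The log2 ratios of these 24 loci, where 5 RPM is added after scaling, shifted by −0.20 to 0.17 under TMM and by −0.49 to −0.03 under size factors.

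**Figure D1:**
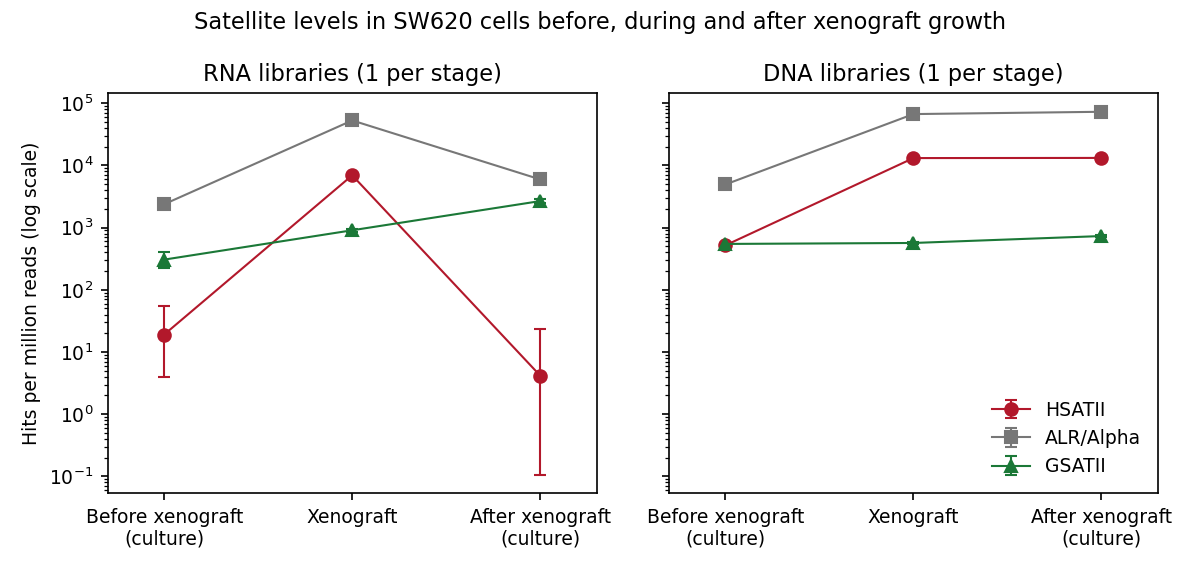
Level in RPM (log scale) of HSATII, ALR/Alpha and GSATII in the RNA (left) and DNA (right) libraries, 1 library per stage, with bars for 95% counting intervals. HSATII RNA stands at 6908 RPM in the xenograft and at 19.1 and 4.17 RPM in the cultures, while HSATII DNA stands at 518, 13066 and 13143 RPM; scaling over satellite loci makes the first DNA step 8.20 to 8.90 times smaller and turns GSATII DNA to below its first value.

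After return to culture, HSATII RNA was at 4.17 RPM (1 hit, 0.105 to 23.2), 1658-fold lower than in the xenograft (298 to 65503). Alpha satellite RNA was 8.87-fold lower (8.41 to 9.35), (GAATG)n 63.9-fold (33.6 to 140), (CATTC)n 37.7-fold (22.0 to 71.0), SAR 188-fold (33.6 to 7424) and HSATI 46.1-fold (8.18 to 1829). The gamma satellites GSATII and GSATX went the other way. GSATII RNA was 2.95-fold higher after the xenograft (2.66 to 3.26; 904 and 2662 RPM) and GSATX 2.65-fold (2.14 to 3.26), or 1.85-fold and 1.66-fold under TMM. GSAT was at 1.67 (1.20 to 2.28), HSAT4 at 1.84 (1.21 to 2.74) and REP522 at 1.64 (1.32 to 2.04), but TMM brought these to 1.04, 1.15 and 1.03.

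ACRO1 RNA was 5.36-fold lower after the xenograft (3.88 to 7.63), CER 11.0-fold (5.74 to 24.2), SATR1 6.84-fold (4.11 to 12.3), SATR2 4.58-fold (2.69 to 8.49) and BSR/Beta 1.86-fold (1.69 to 2.05). D20S16 and HSAT5, with 2 hits and 1 hit after the xenograft, were 5.57-fold (1.46 to 47.2) and 7.79-fold (1.31 to 317) lower. For the other 6 families the interval held 1. SST1 was at 0.816 (0.652 to 1.01) and TAR1 at 0.898 (0.637 to 1.24), but scaling took both further from 1, to 0.511 and 0.563 under TMM and 0.611 and 0.673 under size factors. LSAU was at 0.808 (0.349 to 1.66), or 0.506 and 0.606 when scaled, and MSR1 at 0.299 (0.0347 to 1.18), or 0.188 and 0.224. SUBTEL_sa had 1 hit in each library, and HSAT6 had 0 hits against 5. Of 429 loci, 78 were at least 2-fold higher and 297 lower, a split of 31 and 326 under TMM. Of the 372 at 20 RPM in the xenograft, 45 were higher and 297 lower. TMM shifted the log2 ratio of every family by −0.67 (size factors −0.42) and left the 18 families with intervals off 1 on the same side of it; the named loci shifted by −0.65 to −0.17 (size factors −0.41 to 0.03). The 12 highest log2 ratios (1.88 to 2.31) belonged to 7 GSATII, 3 BSR/Beta and 2 alpha satellite loci, and the 12 lowest (−10.05 to −7.29) to alpha satellite arrays, led by one on the unplaced contig Un_gl000226 with 89.0, 5295 and 0 RPM.

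Between the cultures, no difference in HSATII RNA was detectable at this depth: 1 hit after the xenograft against 3 before gave a ratio of 0.218 (0.00416 to 2.72). GSATII RNA was 8.73-fold higher after the xenograft (6.50 to 11.96; 305 and 2662 RPM) and GSATX 10.6-fold (5.41 to 23.6), or 4.85-fold and 5.87-fold under TMM and 4.59-fold and 5.55-fold under size factors. ALR/Alpha was 2.50-fold higher (2.23 to 2.81), BSR/Beta 2.65-fold (2.15 to 3.28) and REP522 2.304-fold (1.55 to 3.50). Scaling left less of these: 1.39, 1.47 and 1.28 under TMM and 1.32, 1.39 and 1.21 under size factors. GSAT was at 1.84 (1.08 to 3.23) and SST1 at 1.62 (1.11 to 2.40), but scaling by size factors turned both, to 0.965 and 0.853, and TMM turned SST1, to 0.901. SATR2 was lower at 0.437 (0.206 to 0.901) and D20S16, with 2 and 7 hits, at 0.187 (0.0190 to 0.983). For the other 15 families, HSATII included, the interval held 1 or, for HSAT6 with 0 hits in both, there was none. ACRO1 was at 0.778 (0.473 to 1.29) and TAR1 at 0.797 (0.504 to 1.27), but scaling took both below those intervals, to 0.432 and 0.443 under TMM and 0.409 and 0.419 under size factors. SATR1 was at 0.492 (0.234 to 1.01), CER at 0.590 (0.212 to 1.62) and (CATTC)n at 2.84 (0.780 to 15.5), or 0.273, 0.328 and 1.58 under TMM and 0.259, 0.310 and 1.49 under size factors. LSAU, HSAT5 and SUBTEL_sa, with 9, 1 and 1 hits after the xenograft, were at 1.97 (0.491 to 11.3), 0.328 (0.00555 to 6.29) and 0.218 (0.00416 to 2.72). HSAT4 was at 1.81 (0.940 to 3.73) and (GAATG)n at 1.47 (0.412 to 6.55), but size factors turned both, to 0.955 and 0.776, and TMM turned (GAATG)n, to 0.819. HSATI, SAR and MSR1 had 0 hits in the culture before and 1, 1 and 2 after it, so they have no ratio.

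Of the 27 GSATII loci at 20 RPM or more in either culture, 22 were at least 2-fold higher afterwards, and the same held for all 4 GSATX loci and for 57 of 74 alpha satellite loci. The highest was the GSATII locus at chromosome 2, 132511066 to 132514594, with 0, 69.6 and 233 RPM, at least 12.2-fold higher (lower 95% limit 9.63). Of the 12 highest log2 ratios (3.77 to 5.57), 9 were GSATII and 3 alpha satellite. Some of these GSATII loci may share reads. Those at chromosome 22, 16096912 to 16097983, and Un_gl000244, 15910 to 16982, had equal values in all RNA libraries, with 36 hits against 1. Counts of GSATII loci may therefore hold the same reads more than once. The 12 lowest (−4.23 to −0.57) held 6 alpha satellite and 3 ACRO1 loci. In all, 104 of 145 loci were higher and 11 lower, against 68 and 29 under TMM and 67 and 29 under size factors. The count test, which compares these libraries only, called 38 loci higher and 1 lower. Of the 40 at 20 RPM in the culture before, a choice that favours lower values afterwards, 14 were higher and 11 lower. Scaling shifted the log2 ratio of every family by −0.85 (TMM) and −0.93 (size factors), and those of the named loci by −0.79 to −0.31 and −0.87 to −0.41. With no RPM minimum the balance turned, with 210 loci higher and 251 lower.

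**Figure D2:**
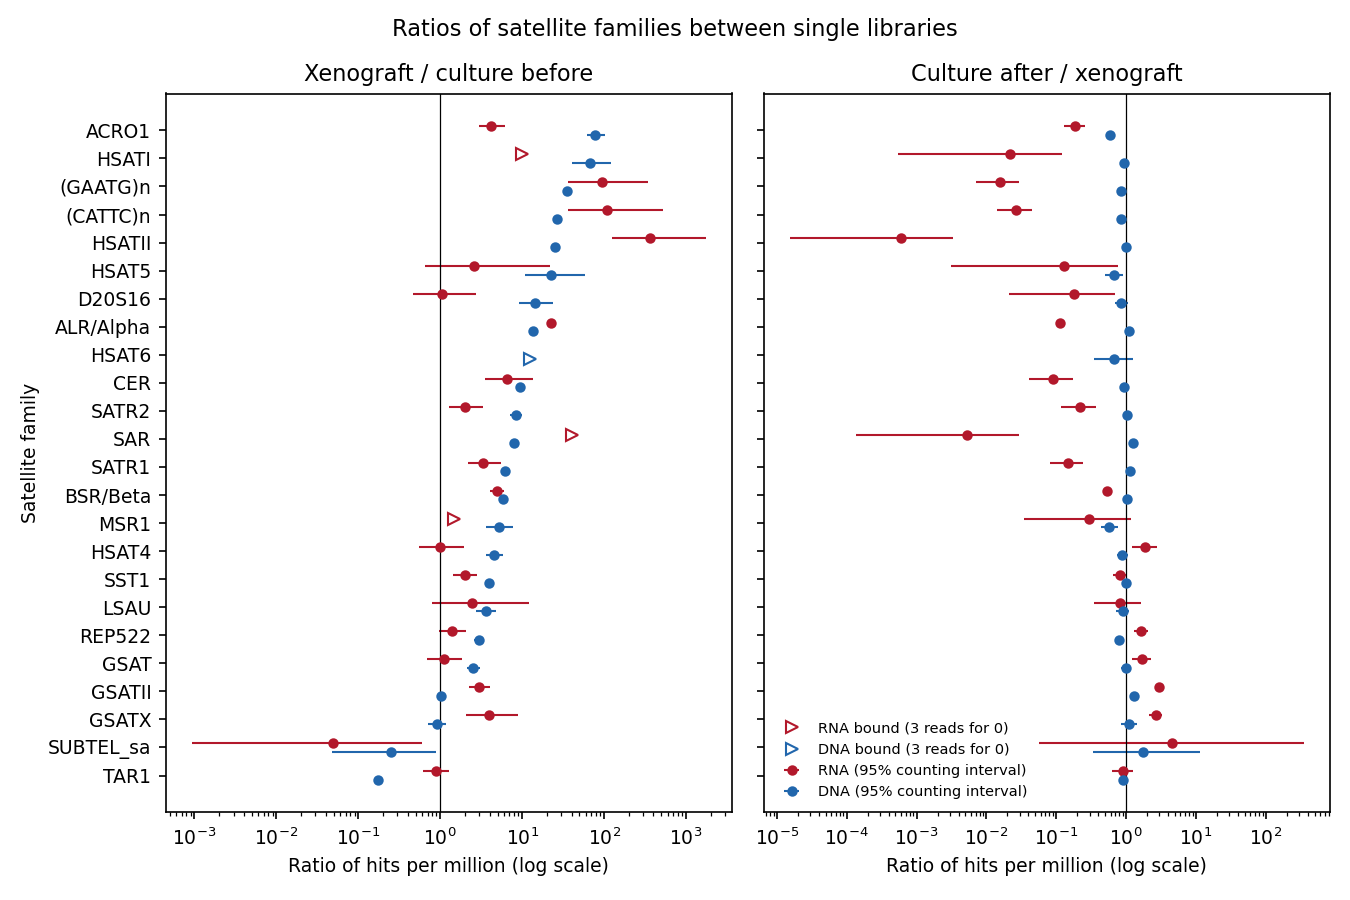
Ratio of RPM (log scale) for each of the 24 satellite families, xenograft over the culture before (left) and culture after over xenograft (right), in RNA (red) and DNA (blue), with 95% counting intervals and open triangles for bounds taken with 3 reads in place of 0. In DNA, 20 families have intervals above 1 on the left, of which 10 cross to below 1 under scaling by size factors and 9 under TMM (as does GSATII, whose interval holds 1), and on the right the DNA points gather around 1 while HSATII RNA lies farthest below it.

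HSATII DNA was at 518 RPM before xenografting (2256 hits, 497 to 540) and at 13066 RPM in the xenograft (42219 hits, 12942 to 13191), 25.2-fold higher (24.2 to 26.3). All 99 HSATII loci at 20 RPM or more were at least 2-fold higher, 6 of which were at 20 RPM in the culture before. The ratio was 51.3 (47.1 to 56.0) on chromosome 16, 24.0 (21.0 to 27.7) on chromosome 2, 25.6 (21.0 to 31.4) on chromosome 7 and 15.1 (14.3 to 16.03) on chromosome 10. The 5 highest log2 ratios of all loci (5.04 to 5.32) were HSATII loci of chromosome 16, such as 46406453 to 46408125 with 2.53 RPM before and 295 RPM in the xenograft, and 46400292 to 46403436 with 7.35 and 473 RPM.

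HSATII was 1 of 20 families with DNA intervals above 1. ACRO1 was 78.1-fold higher in the xenograft (61.2 to 101), HSATI 66.7-fold (40.2 to 120) and (GAATG)n 35.1-fold (32.1 to 38.5), all 3 with intervals wholly above that of HSATII, and (CATTC)n was 26.6-fold higher (24.5 to 28.9). HSAT5 was 22.7-fold higher (10.7 to 57.7), D20S16 14.4-fold (9.11 to 24.1), ALR/Alpha 13.5-fold (13.3 to 13.7), CER 9.52-fold (8.42 to 10.8) and HSAT6 at least 12.6-fold (lower 95% limit 9.57). Much less of this was left under TMM and size factors in that order: 9.52-fold and 8.77-fold for ACRO1, 8.13 and 7.49 for HSATI, 4.28 and 3.94 for (GAATG)n, 3.24 and 2.99 for (CATTC)n, 2.77 and 2.55 for HSAT5, 1.76 and 1.62 for D20S16, 1.65 and 1.52 for ALR/Alpha, 1.16 and 1.07 for CER, and 1.17 and 1.08 for the lower limit of HSAT6. The families SATR2 (8.40), SAR (7.89), SATR1 (6.23), BSR/Beta (5.80), MSR1 (5.25), HSAT4 (4.59), SST1 (3.93), LSAU (3.65), REP522 (2.997) and GSAT (2.53) also had higher values, but all 10 turned to below 1 under scaling by size factors and all but SATR2 under TMM. GSATII was at 1.04 (0.974 to 1.10) and GSATX at 0.921 (0.716 to 1.18), but scaling set both far below 1, at 0.126 and 0.112 under TMM and 0.116 and 0.103 under size factors. TAR1 was 5.70-fold lower in the xenograft (5.10 to 6.37), and SUBTEL_sa, with 16 and 3 hits, 3.96-fold (1.13 to 21.2); as ratios, scaling moved TAR1 from 0.176 to 0.0214 (TMM) and 0.0197 (size factors), and SUBTEL_sa from 0.253 to 0.0308 and 0.0284. The 5 lowest log2 ratios (−4.70 to −2.07) were 4 TAR1 copies of chromosome 9, such as 42805767 to 42806343 with 198 RPM before and 2.79 RPM in the xenograft, and the alpha satellite locus at chromosome 5, 160467064 to 160467247, with 35.6 and 4.64 RPM.

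Scaling over satellite loci removes the difference that these families share: it shifted the log2 DNA ratio of every family by −3.04 (TMM) or −3.15 (size factors) and left HSATII 3.08-fold or 2.83-fold higher. The count of loci moved from 398 higher and 9 lower of 444 to 131 and 137 under TMM and to 111 and 144 under size factors. Of the 75 loci at 20 RPM in the culture before, 38 were higher and 9 lower. The HSATII ratio was 39.7-fold without chromosome 10 and 14.0-fold at the locus with the most xenograft HSATII RNA, which lies on chromosome 10.

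DNA of the culture after the xenograft lay close to that of the xenograft. HSATII DNA was at 13143 RPM (40491 hits, 13015 to 13271), 1.006 times the xenograft value (0.992 to 1.02), and 0 of 473 loci differed 2-fold on the log2(RPM + 5) scale. With no pseudocount, 4 were at least 2-fold higher and 4 lower, by at most 2.10-fold. ALR/Alpha was at 1.09 times the xenograft value (1.08 to 1.10), SAR at 1.24 (1.20 to 1.28), SATR1 at 1.13 (1.06 to 1.21), GSATII at 1.29 (1.21 to 1.37) and BSR/Beta at 1.02 (1.001 to 1.05). ACRO1 was 1.67-fold lower (1.59 to 1.77) and MSR1 1.74-fold (1.31 to 2.32). HSAT5 was at 0.675 (0.4995 to 0.909), REP522 at 0.785 (0.695 to 0.886), (CATTC)n at 0.852 (0.829 to 0.875), (GAATG)n at 0.856 (0.834 to 0.878) and CER at 0.9301 (0.873 to 0.991), and for 12 families, HSATII included, the interval held 1. Of these, D20S16 was at 0.858 (0.698 to 1.05), HSAT4 at 0.886 (0.747 to 1.05), LSAU at 0.896 (0.723 to 1.11), TAR1 at 0.917 (0.786 to 1.07), HSATI at 0.940 (0.845 to 1.05), SATR2 at 1.04 (0.955 to 1.13) and GSATX at 1.11 (0.845 to 1.45). SUBTEL_sa and HSAT6, with 5 and 18 hits after the xenograft, were at 1.75 (0.340 to 11.3) and 0.674 (0.351 to 1.26), and GSAT (0.999) and SST1 (0.987) turned to above 1 under TMM (1.04 and 1.03) and size factors (1.05 and 1.03). The 5 lowest log2 ratios (−0.93 to −0.85) were ACRO1 loci of chromosome 4, and the 5 highest (0.78 to 0.90) were 3 BSR/Beta, 1 alpha satellite and 1 SATR1 locus.

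Against the culture before, the culture after the xenograft held 25.4-fold more HSATII DNA (24.3 to 26.5), or 3.23-fold under TMM and 2.98-fold under size factors. HSATI was 62.7-fold higher (37.7 to 113), ACRO1 46.6-fold (36.5 to 60.5), (GAATG)n 30.03-fold (27.4 to 32.9), (CATTC)n 22.7-fold (20.8 to 24.7) and ALR/Alpha 14.7-fold (14.5 to 14.9), which TMM and size factors brought to 7.99 and 7.37, 5.94 and 5.49, 3.83 and 3.53, 2.89 and 2.66, and 1.88 and 1.73. HSAT5 was 15.3-fold higher (7.10 to 39.5), D20S16 12.4-fold (7.77 to 20.8), SAR 9.77-fold (9.13 to 10.5), CER 8.86-fold (7.82 to 10.1) and SATR2 8.71-fold (7.46 to 10.2). HSAT6 was at least 8.48-fold higher (lower 95% limit 6.22), but its limit turned to 0.792 under TMM and 0.731 under size factors. Under TMM, HSAT5 was at 1.96, D20S16 at 1.58, SAR at 1.24, CER at 1.13 and SATR2 at 1.11, and under size factors at 1.81, 1.46, 1.15, 1.04 and 1.02. The families SATR1 (7.06), BSR/Beta (5.93), HSAT4 (4.07), SST1 (3.88), LSAU (3.27), MSR1 (3.02), GSAT (2.53), REP522 (2.35) and GSATII (1.34) also had higher values, but all 9 turned to below 1 under both, GSATII to 0.171 and 0.157. GSATX was at 1.02 (0.795 to 1.30), or 0.130 and 0.120 when scaled, and SUBTEL_sa at 0.442 (0.127 to 1.26), or 0.0563 and 0.0520. TAR1 was 6.21-fold lower (5.53 to 6.998), a ratio of 0.161 that scaling moved to 0.0205 and 0.0189.

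In DNA after against before, 423 of 459 loci were higher and 8 lower, against 148 and 126 under TMM and 128 and 132 under size factors. The 5 highest log2 ratios (5.18 to 5.35) were 4 HSATII loci of chromosome 16 and the alpha satellite array at chromosome 17, 22241552 to 22263006, with 41.8 RPM before and 1726 RPM after. The 5 lowest (−4.68 to −2.48) were the same 5 loci as in the xenograft. This comparison shares its first library with that of the xenograft, and its second differs little from the xenograft library, so it is no independent measurement.

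RNA was also set against DNA of the same stage. HSATII RNA was 0.0368 times HSATII DNA in RPM before xenografting (0.00759 to 0.108), 0.529 times in the xenograft (0.516 to 0.542) and 0.000317 times after it (8.02e-06 to 0.00177). ALR/Alpha RNA was 0.482 times its DNA before (0.434 to 0.534), 0.790 times in the xenograft (0.783 to 0.798) and 0.0819 times after (0.0776 to 0.0862). Its RNA was higher after than before (2371 and 5932 RPM), so the lower ratio comes from its DNA (4922 and 72474 RPM). In deposited RPM, DNA of the culture before lay below later DNA in most families, which raises the ratios of that stage against later ones. The ratio of GSATII RNA to its DNA was 0.560 (0.412 to 0.745) before, 1.60 (1.48 to 1.73) in the xenograft and 3.65 (3.34 to 3.99) after. Across the 903 loci with 30 or more xenograft DNA hits, which are not independent replicates, xenograft RNA had a Spearman correlation of 0.856 with xenograft DNA, or 0.757 (median of 100 draws) when thinned to the total of the RNA library before xenografting. The same correlation was 0.214 for RNA of the culture before and 0.146 for RNA of the culture after, which held 430 and 1831 hits at these loci. Thinned to those numbers of hits, xenograft RNA had median correlations of 0.437 (0.364 to 0.505 over 100 draws) and 0.591 (0.540 to 0.636). At the same loci, DNA of the cultures before and after had correlations of 0.628 and 0.928 with xenograft DNA. RNA of the culture before was thus set against a DNA profile that differed from that of its own stage.

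**Figure D3:**
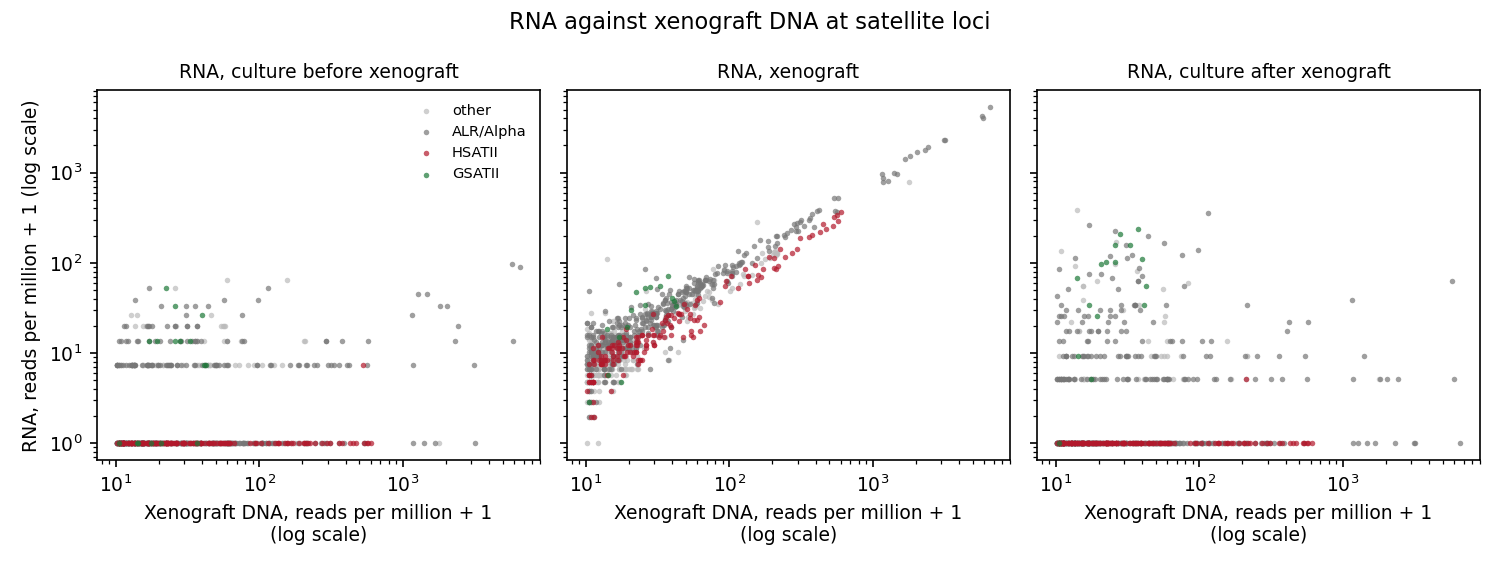
RNA of each stage (RPM + 1, log scale) against xenograft DNA (RPM + 1, log scale) at 903 satellite loci with 30 or more xenograft DNA hits, 1 point per locus, with HSATII in red, GSATII in green, ALR/Alpha in dark grey and other families in light grey. Points of the xenograft RNA follow the DNA (Spearman correlation 0.856), while most HSATII loci lie at 0 in both cultures, whose correlations are 0.214 and 0.146.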

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

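Some alternatives were chosen after seeing the data, and the others were fixed before. Chosen after were leaving out the loci of chromosome 10 or 16 and the single locus with the most xenograft HSATII RNA. So were identical loci counted once, no pseudocount and the count test. No paired analysis was possible because each group holds 1 library, and for the same reason no library could be left out. The medians of gene lists were not run, since the table holds 0 gene rows. The 3 ratios of HSATII RNA stayed within their counting intervals under each alternative run, as did those of HSATII DNA with identical loci counted once. For HSATII RNA this could hardly be otherwise and shows little. Scaling moved RNA ratios by 1.13 to 1.90 times, and these intervals are far wider. The RNA size factors rest on the 211 loci with a read in all 3 RNA libraries. Depth limits the culture RNA most, where HSATII rests on 3 hits and 1 hit. Where a value below differs, the cause was not tested, except that in DNA scaling over satellite loci removes by construction what most satellites share. In RNA of the xenograft against the culture before it did not: 361 loci were still higher and 12 lower under TMM.

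HSATII DNA of the xenograft against the culture before was 3.08-fold under TMM, 2.83-fold under size factors and 27.8-fold with totals without satellite hits. It was 14.0-fold at the locus with the most xenograft HSATII RNA, which lies on chromosome 10. It was 17.2-fold without chromosome 16 and 39.7-fold without chromosome 10. For the culture after against the culture before, the same settings gave 3.23, 2.98, 28.1, 13.4, 17.3 and 40.0. For the culture after against the xenograft, TMM and size factors gave 1.05 each and the locus with the most xenograft HSATII RNA 0.960.

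Counts of loci with a 2-fold difference moved with the RPM minimum. In RNA, the counts with no minimum and with a minimum of 50 RPM were 1097 and 170 (main count 340) for xenograft against the culture before, 1028 and 214 (375) for culture after against xenograft, and 461 and 59 (115) for the cultures. With no minimum, 1 hit in the culture before (6.36 RPM) against 0 already passes 2-fold and 1 hit in the culture after (4.17 RPM) does not. In DNA they were 1298 and 213 (407) for xenograft against the culture before and 1293 and 222 (431) for the cultures. TMM and size factors gave 268 and 255 for the first of these DNA comparisons and 274 and 260 for the second. DNA after against the xenograft had 0 loci, 3 with a pseudocount of 1 RPM, 8 with no pseudocount and 1 with no minimum. At an adjusted p under 0.05, the count test on recovered reads called 165, 259 and 39 loci in RNA. In DNA it called 2718, 56 and 2555. It compares these libraries and not the conditions. In RNA, 165 loci were higher and 0 lower in the first comparison, 49 and 210 in the second, and 38 and 1 in the third.

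Family ratios in DNA of xenograft against the culture before turned, under TMM and size factors in that order, for BSR/Beta (0.707, 0.652), GSAT (0.309, 0.285), HSAT4 (0.560, 0.516), LSAU (0.445, 0.409), MSR1 (0.640, 0.589), REP522 (0.366, 0.337), SAR (0.962, 0.886), SATR1 (0.760, 0.7002) and SST1 (0.480, 0.442), and for SATR2 under size factors (0.943). For the culture after against the culture before they turned for BSR/Beta (0.756, 0.698), GSAT (0.323, 0.298), GSATII (0.171, 0.157), HSAT4 (0.518, 0.478), LSAU (0.416, 0.384), MSR1 (0.385, 0.355), REP522 (0.2996, 0.277), SATR1 (0.899, 0.830) and SST1 (0.495, 0.457). In RNA of the cultures, SST1 turned under both (0.901, 0.853) and GSAT under size factors (0.965). These lists hold only families whose intervals excluded 1. Ratios whose intervals held 1 also crossed it under scaling, such as (GAATG)n RNA of the cultures and GSATII DNA of xenograft against the culture before. None of the 102 named loci changed sign under scaling or with a pseudocount of 1 RPM. As they were picked for the highest and lowest ratios, this could hardly be otherwise and shows little.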

Other observations

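The test of depth and that of DNA carried into RNA were set down before their results were seen; the other tests in this part were chosen after. The families differed in how far RNA stood from the DNA of the same stage. GSATX RNA was 1.55 times its DNA before xenografting (0.695 to 3.01), 6.70 times in the xenograft (5.33 to 8.47) and 16.04 times after it (12.5 to 20.7). REP522 RNA was 3.24 (2.19 to 4.66), 1.52 (1.32 to 1.74) and 3.17 times its DNA (2.57 to 3.90). ACRO1 RNA was 13.4 (8.51 to 20.8), 0.717 (0.667 to 0.771) and 0.224 times its DNA (0.158 to 0.308). The fall for ACRO1 comes mainly from its DNA, at 15.2, 1183 and 707 RPM. Its RNA stood at 203, 849 and 158 RPM. TAR1 RNA stood at 235, 209 and 187 RPM at the 3 stages and TAR1 DNA at 643, 113 and 104 RPM; 4 copies of chromosome 9 held 198, 153, 135 and 80.1 RPM of the first DNA value.

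Xenograft RNA followed the DNA profile locus by locus, with a Spearman correlation of 0.856 against 0.214 for RNA of the culture before. Thinned to the total of that culture library, 100 draws of the xenograft RNA gave a median of 0.757 (0.721 to 0.787) and 1086 HSATII hits (1010 to 1164), where 3 were observed, but far more satellite hits were left than the 793 of the culture. Thinned to the culture's 430 hits at the loci compared, the median was 0.437 (0.364 to 0.505), so fewer hits account for part of the difference in correlation and not for all of it. Genomic DNA carried into the xenograft RNA library may also give such a profile, and it would dilute loci transcribed in culture; at 38 loci with 3 or more RNA reads before and less DNA than RNA, xenograft RNA was 0.442 times that of the culture after (0.399 to 0.490). Carry-over also predicted an even RNA to DNA ratio, set down as spanning no more than 2 times the span between the later DNA libraries. Over 6 families with culture RNA under 10% of xenograft DNA it spanned 1.91 times, against 1.45 times, which met this. They were HSATII, (CATTC)n, (GAATG)n, SAR, HSATI and ALR/Alpha. Against DNA of the same stage before xenografting, RNA of (CATTC)n, (GAATG)n and ALR/Alpha was higher, at 0.141, 0.226 and 0.482 times. HSATI, with 0 RNA hits there, had an upper limit of 7.72. Yet the mirrored ratio, added once the first value was known, was 1.88 against the culture before (1.66 to 2.13 over 152 loci). Dilution and a gain can therefore not be told apart here. At 598 loci without a read in either culture RNA library, xenograft RNA was 0.666 times xenograft DNA (0.656 to 0.675), which leaves both DNA in the library and broad satellite transcription in the tumour open, the second untested with 1 library per group.

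In deposited RPM, DNA of the culture before lay below both later DNA libraries in most families. Scaling over satellite loci removes by construction what most satellites share. For the xenograft it turned several families to below 1, such as SST1 (0.480 under TMM), and left others higher, such as ACRO1 (9.52) and HSATI (8.13). A gain of HSATII copies alone would leave the other families in place, yet 19 of them had intervals above 2-fold, and mouse tissue reads present only in the tumour would be lost in culture, yet HSATII DNA stayed at 1.006 times the xenograft value. If every read with more than 1 match had been left out of the first library alone, loci of 1 family and length with identical counts (5 hits or more) in both later libraries would be nearly empty in it; over all 83 such sets it held 280 hits, 1.38 times those expected from their families (1.23 to 1.56), and over the 18 HSATII sets 24 hits, 0.854 times (0.547 to 1.27). Of the 83 sets, 31 held no hit in the first library and 11 held 5 or more. The pooled test replaced earlier forms limited to sets with 5 or more hits in the first library. There, 9 of 11 sets of equal length were identical in it, and 5 of 24 sets of any length with 20 or more hits in each later library. A limit on reads with very many matches, a preparation of the first library that lost satellite DNA, and a difference in the cells remain possible, each untested here.

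HSATII DNA differed between chromosomes, with a xenograft ratio of 51.3 on chromosome 16 and 15.1 on chromosome 10. More copies of all of chromosome 16 would raise its alpha satellite too. The alpha satellite ratio of chromosome 16 was 0.455 times that of chromosome 10 (6.22 and 13.7). However, reads with several matches may be counted on more than 1 chromosome. Among sequences with 100 or more alpha satellite hits in xenograft DNA, this ratio ran from 5.01 (chromosome Y) to 23.9 (19_gl000208_random). The test can therefore not exclude a gain of chromosome 16. A few loci with many reads do not carry the difference in HSATII. Among HSATII loci with 30 or more xenograft DNA hits, identical loci were counted once and 0.5 RPM was added to both values. The median log2 ratio was 4.75 on chromosome 16 (68 of 156 loci, quartiles 4.16 to 5.58). On chromosome 10 it was 3.78 (29 of 47, 3.66 to 3.96), a difference of 0.97. Loci with fewer hits were left out of this test. Differences in sequence between the HSATII arrays, on which both matching and recovery of reads may depend, and unequal gain of the arrays were not tested.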
